A study of Escherichia coli with 2 samples.

How the data were processed

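The study sequenced total RNA from 2 samples of Escherichia coli, whose strain is given in the labels as k12f, at mid-log (8 h) and late-log (14 h) growth, with 1 library per stage. Cells were grown at 37 °C with shaking, pelleted and extracted with TRIzol, and libraries were made with a NEBNext Ultra II DNA kit, per the labels' protocols. Groups and times were taken from the labels.

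Bowtie2 and DESeq are named, without versions or roles, in the submitters' processing notes. The reference genome, the annotation, the counting, any filter, and the normalization are not given in the sources used here. The table of the comparison holds 3881 genes by locus tag, each with the authors' deposited log2 fold change and the authors' deposited FDR. The FDR, from 0 to 0.995, was treated as an adjusted p-value. Its smallest values argue against a Benjamini-Hochberg adjustment, as described under the other observations. Which library is the numerator of the log2 fold change is not stated in the table of the comparison, so signs are given as deposited. The pathway list holds, for 67 KEGG pathways, a deposited enrichment factor, treated as a ratio, and a deposited corrected p-value, without member genes. No values per library and no counts were analysed here. The depth of each library is therefore unknown, no counting interval can be given for a gene, and the low-count genes cannot be removed. A fold change can rest on few reads, and a scaling that is off by a constant would move all genes in 1 direction.

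Locus tags were matched to gene symbols and to the gene order of the RefSeq gene table of assembly ASM584v2, which was used for names and neighbours alone because the build of the deposited values is not named. Of 3881 locus tags 3878 matched, and 773 of 4651 annotated genes were not analysed here. The matched genes comprise 3771 protein-coding, 51 tRNA, 44 ncRNA and 9 rRNA genes, 2 pseudogenes and 1 other.

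Calls are genes with an FDR under 0.05. The 40 gene lists were fixed before the data were examined; 39 have members in the table, 751 genes are in any list and 13 in more than 1. Members were matched by current symbol, and 2 through an older symbol. Each list of at least 3 genes was described by its median log2 fold change and the percentile of that median among 10000 random lists of as many genes (seed 7). A list was said to lie outside when its median was beyond the central 95% of those medians. Because no expression levels were analysed here, the random lists could not be matched on mean expression as had been planned. Runs are adjacent genes of the annotation order with the same call. The distance from the origin was counted in genes from the interval between mnmG and mioC.

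The rule for named genes, set before the data were examined, used counts. It was replaced, after the data were seen, by the 12 highest and 12 lowest called genes, up to 4 called members with the largest absolute log2 fold change in each list outside the random range and up to 2 in each other list, and the fixed markers rpoS, dps, rmf, fis, rpsA, osmY and cspA. Of the genes that this rule names, 1 is not reported here. Genes named outside this rule were chosen after their values were seen. These are mglB, rbsD, fruA, lacZ, ldhA, dnaK, groL, ompC, rrlG, flhE, wcaA and the genes of the first paragraphs of the other observations.

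The alternatives set before the data were examined and run here were a 4-fold limit, recentring on the median of genes outside the ribosomal proteins, leaving out rRNA and tRNA genes, an FDR under 0.01 with a 2-fold change, the mean of a list in place of its median, 1 value per run of adjacent list members, and the origin trend without ribosomal proteins. An FDR under 0.001, a shared size limit for both signs, a KEGG limit of 0.01 and lists moved along the gene order were added after seeing the data.

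The list and run steps were tested on simulated data from the 3878 ordered genes, with their log2 fold changes shuffled among genes. Neighbouring genes were thus not alike, so the share of lists called without a shift holds for independent genes only. Runs were planted among genes without a call, so finding them checks the code alone. With 15 members shifted by 1 on the log2 scale, 12 of 20 lists were called high, 1 of 20 lists with no shift was called, and 10 of 10 planted runs of 5 genes were recovered. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.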

Results

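Total RNA of Escherichia coli was sequenced at 2 points of growth in shaken culture at 37 °C, mid-log (8 h) and late-log (14 h), with 1 library for each stage. The comparison asks which genes differed in transcript level between the stages. The data are the authors' deposited table of 3881 genes with a log2 fold change (log2FC) and a value headed FDR for each, and the authors' deposited list of 67 KEGG pathways. Neither gives a value per library, so the depth of the libraries is unknown. The authors' deposited table does not state which library is the numerator of the log2FC, so a positive value means a higher level in the numerator library, whichever stage that is. With 1 library per stage no difference has a replicate check, and each FDR compares these 2 libraries, not the growth stages. Genes with an FDR under 0.05 are referred to as called, a limit chosen here. Calls, list medians, means and percentiles below were computed here from the authors' deposited values and are not the authors' own.

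The highest values in the authors' deposited table were 9.35 for tnaA (b3708, 652-fold), which encodes tryptophanase, and 9.21 for gatZ (b2095, 594-fold) and 8.18 for gatY (b2096, 291-fold), which serve galactitol breakdown. The outer membrane proteins ompW (b1256) and ompF (b0929) had 7.80 and 7.43, the tryptophan transporter tnaB (b3709) 7.35, and the galactose gene galT (b0758) 7.22, all in the authors' deposited table. High called values there also belonged to ydcH (b1426, 7.98), ychH (b1205, 7.61), yegT (b2098, 7.29) and the small RNA ryeA (b4432, 7.78). Each of these genes has an FDR listed at 0 in the authors' deposited table. The ryeA gene overlaps another small RNA gene on the opposite strand. The library kit named in the labels is a DNA kit, and whether strand was kept is not given in the sources used here. Reads of the pair may therefore not have been told apart.

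At the other end of the authors' deposited table, the nitrate-responsive gene yeaR (b1797) had −9.49 (719-fold, FDR 8.66e-10) and its neighbour yoaG (b1796) −6.63 (FDR 2.91e-05). The acid resistance regulator adiY (b4116) had −6.95 (FDR 9.30e-06) and the arginine exporter argO (b2923) −6.12 (FDR 1.44e-06) in the authors' deposited table. The remaining 8 of the 12 lowest called values there belonged to yebO (b1825, −5.58), yjcB (b4060, −5.32), yciF (b1258, −5.29), bglJ (b4366, −5.16), yhdV (b3267, −5.05), the glutaredoxin gene grxA (b0849, −5.04), the phosphate transporter gene pstB (b3725, −4.98) and the acid shock gene asr (b1597, −4.90).

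Over all 3881 genes of the authors' deposited table, 887 had a log2FC of 1 or more and 921 a log2FC of −1 or less, about a median of −0.06 with quartiles at −0.93 and 0.89. Shifted so that the median of genes outside the ribosomal proteins is 0, these numbers became 936 and 877. The authors' deposited table has 509 called genes (13.1%), of which 395 (77.6%) are positive and 114 negative. Called positive values begin at 1.95, whereas the called negative value nearest 0 in the authors' deposited table is −2.69. Of genes with a log2FC of 2 or more, 383 of 393 (97.46%) were called, against 114 of 343 (33.2%) with −2 or less. An FDR of 0 is listed for 57 genes, and all 57 are positive in the authors' deposited table. How the FDR was computed is not given in the sources used here.

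**Figure D1:**
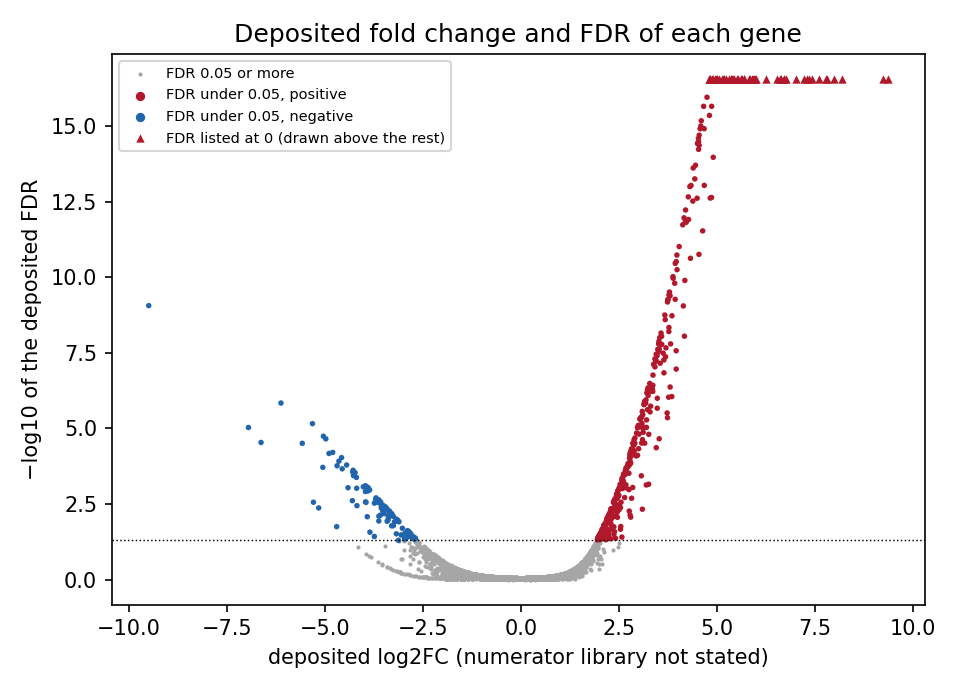
Each point is 1 of the 3881 genes of the authors' deposited table, with its log2FC (numerator library not stated) on the horizontal axis and −log10 of its FDR on the vertical axis; the dotted line is an FDR of 0.05 and triangles are the 57 genes listed at 0. The 395 called positive genes (red) begin at a log2FC of 1.95 and the 114 called negative genes (blue) at −2.69.

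Gene lists were then compared with 10000 random lists of the same number of genes, a description of these 2 libraries and not a test of the stages. Of 39 lists with members in the authors' deposited table, 13 had a median above the central 95% of the medians of random lists. The median lay below that range for 6 lists and within it for 20. By chance 1.95 lists would lie outside if genes varied independently, but neighbouring genes had similar values (Spearman's rho 0.40). Set against the same list moved along the gene order, which keeps adjacent members adjacent, 4 of the lists outside lay within the range. None of the fixed F plasmid transfer genes was analysed here.

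The list of alternative carbon source genes, the list with the most members, had the most called positive genes of the 39 lists. Of 64 genes for the uptake and use of alternative carbon sources, 41 were called positive and 0 negative in the authors' deposited table, with a median of 2.92 (above every random list). Besides gatZ, gatY and galT, the authors' deposited table gives 6.77 for mglB of galactose uptake, 6.52 for rbsD of ribose uptake, 5.81 for fruA of fructose uptake and 5.50 for lacZ, beta-galactosidase, which were named after their values were seen. Amino acid catabolism had 12 called positive of 24 genes and 0 negative, with a median of 1.96 (above every random list). Beside tnaA and tnaB, the authors' deposited table gives 5.34 for aspartase aspA (b4139) and 4.996 for asparaginase ansB (b2957).

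The TCA cycle and respiration lists also had positive medians. In the TCA list 10 of 16 genes were called positive and 0 negative (median 2.70, above every random list), among them the succinate dehydrogenase genes sdhB (3.68), sdhA (3.51) and sdhC (3.31) and citrate synthase gltA (3.15) in the authors' deposited table. For acetate and glyoxylate metabolism 3 of 7 genes were called positive (median 1.82, percentile 99.6), namely aceK (2.73), ackA (2.36) and aceA (2.30) in the authors' deposited table. With 1 value per run of adjacent genes its median was 1.62, within the random range. The aerobic respiratory chain had 10 called positive of 24 (median 1.70, above every random list), all in 1 run of adjacent NADH dehydrogenase I genes from nuoN to nuoE, with 4.81 for nuoM, 4.80 for nuoL, 4.52 for nuoN and 4.45 for nuoJ in the authors' deposited table. With 1 value per run of adjacent genes the median of that list was 0.39 and within the random range. ATP synthase had 4 called positive of 9 (median 1.91, percentile 99.9), which are atpC (3.10), atpD (2.47), atpA (2.22) and atpG (2.10) in the authors' deposited table. Against the same list moved along the gene order, which keeps adjacent members adjacent, its percentile was 96.2. Glycolysis and glucose uptake had 1 called gene of 17, phosphoglycerate kinase pgk (2.49), and a median of 0.85 (percentile 98.5) in the authors' deposited table, and its mean of 0.67 lay within the random range. With 1 value per run its median was 0.61, and moved along the gene order the list was at percentile 97.47, both within the range.

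Genes used without oxygen had positive medians too. Of 28 genes of fermentation and hydrogenases 17 were called positive and 1 negative (median 3.20, above every random list) in the authors' deposited table. The hydrogenase 1 genes hyaB, hyaC and hyaF had 5.68, 5.67 and 5.15 and the alcohol dehydrogenase adhE 5.12, while lactate dehydrogenase ldhA had −3.41 in the authors' deposited table. Anaerobic respiration had 9 called positive of 32 and 0 negative (median 1.16, above every random list). Its highest members were the fumarate reductase genes frdC (5.34), frdB (4.74), frdD (4.67) and frdA (4.66) in the authors' deposited table.

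Of 3 ribosome hibernation genes rmf (b0953, 4.82) and raiA (3.80) were called positive from the authors' deposited values, with a list median of 3.80 (percentile 99.7). The RpoS-dependent list, genes of the stationary phase sigma factor, had 9 called positive, 1 called negative and 42 not called of 52 (median 0.63, percentile 99.8), and its mean of 0.40 lay within the random range. Among its members the authors' deposited table gives 3.64 for ydcT, 3.54 for yeaH, 3.47 for yeaG and −5.29 for yciF. The growth-phase markers rpoS (0.80), dps (−1.15), fis (0.44), rpsA (−0.32), osmY (−1.96) and cspA (−0.20) were not called in the authors' deposited table, with FDR values from 0.434 for osmY to 0.992 for rpsA. Of 9 ribosomal RNA genes 7 were called positive (median 2.23, percentile 99.98) in the authors' deposited table, including rrlH (2.79), rrsG (2.78), rrlA (2.61) and rrsC (2.30). The copies are nearly identical, so the value of any 1 copy is uncertain, and the percentile treats copies as separate genes. Of 22 ribosomal RNA genes of the fixed list, 9 are in the authors' deposited table. The copy rrlG had −1.45 (FDR 0.958, not called), both values equal to those of the unrelated gene flhE, in the authors' deposited table. Tryptophan biosynthesis had 2 called positive of 5, trpE (2.97) and trpA (2.86), and a median of 1.63 (percentile 97.9) in the authors' deposited table, which was at percentile 92.7 when the list was moved along the gene order.

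Iron, phosphate, acid resistance and heat shock genes had negative medians. Of 36 genes of iron acquisition and storage 8 were called negative and 0 positive (median −1.61, below every random list) in the authors' deposited table. The lowest were fecR (−4.02), a regulatory gene of ferric citrate transport, and the enterobactin genes entC (−3.90), fes (−3.70) and fepB (−3.46) in the authors' deposited table. The phosphate starvation list had 5 called negative of 18 (median −0.92, percentile 1.13), all adjacent, among them pstB (−4.98), pstS (−3.65), pstC (−3.18) and phoU (−3.11) in the authors' deposited table. With 1 value per run its median was −0.38 and within the random range. Glutamate-dependent acid resistance had 3 called negative of 14 (median −1.67, percentile 0.05), which are yhiD (−3.95) and the regulators gadW (−3.50) and gadX (−3.36) in the authors' deposited table. Among 20 heat shock genes 1 was called, hslR (−2.91), with a list median of −1.69 (percentile 0.01) in the authors' deposited table. The chaperone genes dnaK (−2.17, FDR 0.803) and groL (−1.69, FDR 0.903) were not called in the authors' deposited table.

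Toxin-antitoxin modules had 0 called of 24 genes and a median of −1.33 (percentile 0.01) in the authors' deposited table. The list of curli, fimbriae and exopolysaccharide genes had a median of −1.11 over 19 members (percentile 0.32), while its 1 called member, the curli subunit csgA, was positive at 2.28 in the authors' deposited table. The low values lay in adjacent colanic acid genes, such as wcaA (−3.88, not called, named after its value was seen). With 1 value per run of adjacent genes the list's median was 0.33 and within the random range. For genes with a log2FC of −1 or less, 174 of 921 (18.9%) shared both values exactly with another gene of the authors' deposited table, against 38 of 887 (4.28%) with 1 or more.

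**Figure D2:**
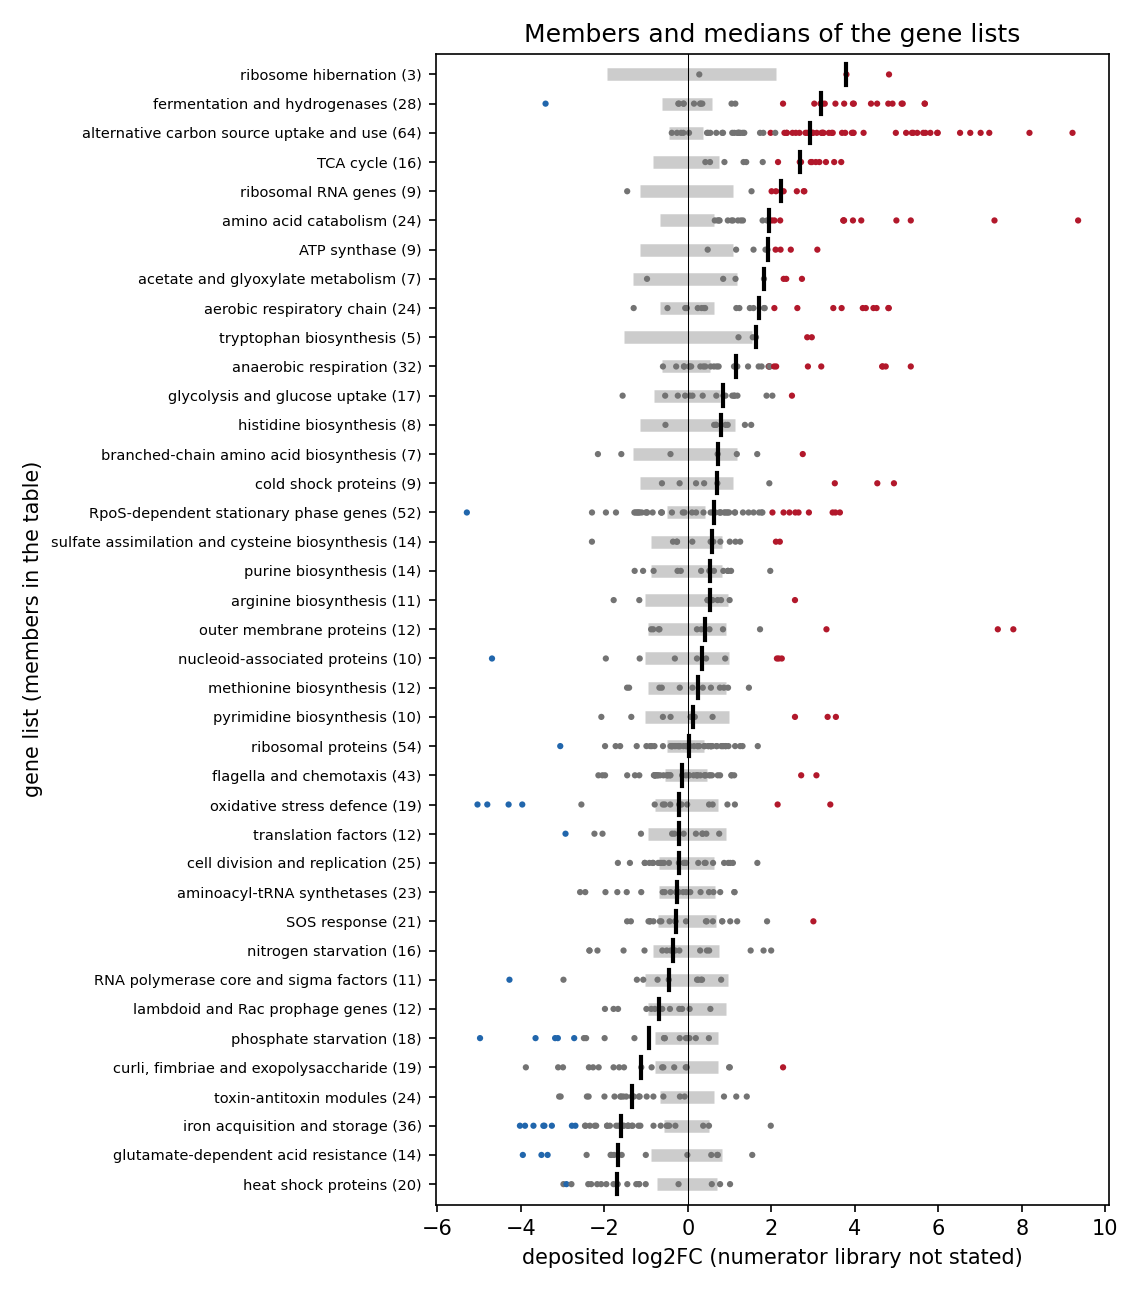
Each row is 1 of 39 gene lists with its number of members in the authors' deposited table; points are members at their log2FC (numerator library not stated; red called positive, blue called negative, grey not called), black bars are medians and grey bands the central 95% of medians of 10000 random lists of the same size. Medians run from −1.69 for heat shock proteins to 3.80 for ribosome hibernation.

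Protein synthesis genes lay within the range of random lists. Ribosomal proteins had a median of 0.03 over 54 genes (percentile 63.8), translation factors −0.21 over 12 and aminoacyl-tRNA synthetases −0.26 over 23 in the authors' deposited table. The first has 1 called gene, rplY (−3.05), and the second infA (−2.93), both negative in the authors' deposited table. RNA polymerase and sigma factors had −0.46 over 11 with 1 called gene, the iron sigma factor fecI (−4.27), in the authors' deposited table. Nucleoid-associated proteins had 0.33 over 10, with 3 called positive, including hupB (2.25), and stpA called negative (−4.69) in the authors' deposited table. Cell division and replication had −0.21 over 25 with 0 called, and flagella and chemotaxis −0.14 over 43 with 2 called, the flagellar master regulator genes flhD (3.08) and flhC (2.72), in the authors' deposited table. Some members of the latter list shared both values exactly with another member, and how many reads they rest on is unknown.

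Biosynthetic lists within the random range had medians in the authors' deposited table of 0.52 for arginine, 0.79 for histidine, 0.72 for branched-chain amino acids, 0.24 for methionine, 0.59 for sulfate assimilation and cysteine, 0.52 for purines and 0.12 for pyrimidines. Their called members named here were carB (2.57), ilvN (2.75), cysU (2.20), cysW (2.11), pyrI (3.55) and pyrB (3.35) in the authors' deposited table. Nitrogen starvation (−0.36), SOS response (−0.29, with tisB called at 3.01) and lambdoid and Rac prophage genes (−0.70) also lay within the range in the authors' deposited table. Outer membrane proteins had a median of 0.42 over 12 with 3 called positive, ompW, ompF and ompC (3.32), and cold shock proteins 0.71 over 9 with 3 called positive, including cspD (4.94) and cspE (4.54), in the authors' deposited table. Oxidative stress defence had 2 called positive and 4 negative of 19, with grxA at −5.04 and the regulator soxR at −4.80, and a median of −0.21 in the authors' deposited table. The means of the last 3 lists, 1.59, 1.71 and −0.78, lay outside the random range.

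The authors' deposited KEGG list has 6 of 67 pathways with a corrected p under 0.05. These are oxidative phosphorylation (corrected p 1.28e-06), the citrate cycle (1.32e-05), toluene degradation (1.34e-05), fructose and mannose metabolism (0.000256), galactose metabolism (0.00641) and the phosphotransferase system (0.00737) in the authors' deposited list. Their enrichment factors run from 0.13 for toluene degradation to 0.34 for the phosphotransferase system in the authors' deposited list, all below 1, and 57 pathways have a corrected p of 1. Of the TCA list fixed here 62.5% of genes were called, against 13.1% of all genes, and the share of all genes over that of the list was 0.21, beside a deposited factor of 0.22 for the citrate cycle. For the respiratory chain and ATP synthase lists together 42.4% were called, a ratio of 0.31 beside 0.24 for oxidative phosphorylation in the authors' deposited list. A factor below 1 is therefore not read here as a lack of called genes. The authors' list gives neither member genes nor a definition of the factor, and it was made by the study from these samples, so it is not independent evidence beside the gene lists.

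Distance from the replication origin was compared with the log2FC of the authors' deposited table across genes, which are not independent replicates. Spearman's rho was 0.07, with a median of −0.27 in the fifth of genes nearest the origin and 0.04 in the farthest. Of 93 other placements of the origin along the gene order, 40 gave a rho as far from 0.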

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

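Lists moved along the gene order, the FDR limit of 0.001, the shared size limit and the KEGG limit of 0.01 were chosen after seeing the data; the other settings were planned. A 4-fold limit left 393 positive and 343 negative genes. An FDR under 0.001 left 249 positive and 27 negative calls, an FDR under 0.01 with a 2-fold change 315 and 70, and a size on both sides of at least that of the called negative value nearest 0 (−2.69) 235 and 114, where the main numbers were 395 and 114; these limits are stricter by construction. The mean gave the same side as the median for 34 of 39 lists. The exceptions were RpoS-dependent genes (0.40) and glycolysis (0.67), now within the random range, and cold shock (1.71), oxidative stress (−0.78) and outer membrane proteins (1.59), now outside it. With 1 value per run of adjacent genes the side was the same for 31 of 36 lists. This put acetate and glyoxylate (1.62), glycolysis (0.61), the aerobic chain (0.39) and phosphate (−0.38) within the range. It turned the sign of curli, fimbriae and exopolysaccharide (0.33, percentile 72.5), which also lay within the range. By construction this setting gives long runs less weight. Moved along the gene order, 35 of 39 lists kept their side, and glycolysis (median 0.85, percentile 97.47), ATP synthase (1.91, 96.2), tryptophan (1.63, 92.7) and phosphate (−0.92, 3.30) lay within the range. For the means the cause was not tested. The KEGG limit of 0.01 left the number of pathways at 6. The origin trend without ribosomal proteins stayed at a rho of 0.07. Total-count and TMM scaling, count filters, pseudocounts, matched random lists, shares of counts, length and GC trends, and KEGG medians were not run, since counts were not analysed here. Depth is unknown, so genes resting on few reads could not be set apart.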

Other observations

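Of the tests below, the one on repeated pairs of values was set before its result was seen, and those on the offset, the runs, the FDR column and the sign after it. Genes named here were chosen after their values were seen.

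Neighbouring genes had similar values. Across 3477 adjacent pairs Spearman's rho of the authors' deposited log2FC was 0.40, against 0.02 for genes 10 rows apart, and 184 adjacent pairs shared a call and its sign. The called genes formed 25 runs of 4 or more, of which 23 were positive, while the highest number in 1000 shuffles of the gene order was 3. Several runs lie outside the fixed lists. The lsr genes for uptake and breakdown of the signal autoinducer-2 formed a run of 8 with a median of 4.76, and lsrB had 5.53 in the authors' deposited table. The phage shock genes pspA to pspE had a median of 4.12, the oligopeptide transporter genes oppA to oppF 3.73 and the dipeptide transporter genes dppF to dppA 2.28. Among negative values, the thiamine biosynthesis genes thiC (−4.57), thiE (−4.64), thiF (−4.20), thiG (−3.36) and thiH (−2.76) were called in the authors' deposited table, and thiS (−2.71, FDR 0.751) was not.

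Some genes of related function had opposite signs. The manganese superoxide dismutase gene sodA had −4.29 and the iron enzyme's gene sodB 3.41 in the authors' deposited table. The ribonucleotide reductase gene nrdE and nrdH, the gene of its electron donor, had −3.33 and −4.18, and nrdD, the gene of the anaerobic enzyme, 3.13 in the authors' deposited table. The small RNAs csrB and csrC, which bind the regulator CsrA, had 5.62 and 3.33 in the authors' deposited table, and rnpB, the RNA of RNase P, 3.26.

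The authors' deposited table has 395 positive and 114 negative calls, although it has 887 genes at a log2FC of 1 or more against 921 at −1 or less (936 against 877 when recentred on genes outside the ribosomal proteins), and 393 at 2 or more against 343 at −2 or less. Whether a constant offset carried alike by the deposited log2FC and the test is the cause cannot be judged from these values. If nothing else differed between the sides, such an offset would leave genes of equal deposited size called equally often. Of genes with a size from 2 to under 4, 286 of 296 positive ones were called (96.6%, 95% exact binomial interval 93.9 to 98.4). Of the negative ones of that size, 85 of 313 were called (27.2%, 22.3 to 32.4). These genes are among those at 2 or more and −2 or less whose shares were seen first, so the comparison restates that difference. The sides also differed in repeated pairs of values, as given below. If that marks unequal read support, the shares called could differ with or without an offset, so no conclusion on an offset is drawn. The comparison also cannot judge an offset that the test carried and the deposited log2FC did not. A few long runs are argued against, since positive runs of any length outnumbered negative ones by 244 to 81, a ratio of 3.01. An offset in whole or in part, an offset carried by the test alone and lower counts behind negative values stay open and may contribute. Of genes with a log2FC of −1 or less 18.9% (95% exact binomial interval 16.4 to 21.6) shared both values with another gene, against 4.28% (3.05 to 5.83) of those with 1 or more. The intervals of this paragraph treat genes as independent and may be too narrow. Neighbouring genes had similar values, and repeats come in sets of up to 10 genes. The link of such repeats to few reads was not tested, since no counts were analysed here, and a biological difference between the stages stays open, untested.

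The column headed FDR in the authors' deposited table may not hold p-values adjusted by the Benjamini-Hochberg step-up. All 28 genes with a value above 0 and under 1e-12 had a whole multiple of 1.11e-16 (within 0.01), the spacing of double-precision numbers just below 1. A step-up multiplies a raw p by the number of genes over its rank, at most 66.9 here after the 57 genes at 0. That product has no reason to be whole, which argues against a step-up for these 28 genes. A number obtained by subtraction from 1, such as a posterior probability, is a candidate explanation that was not tested. No biological explanation was tested.

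The stage that positive values stand for cannot be told apart from these lists. If they meant higher in late-log, RpoS-dependent and ribosome hibernation genes would be expected above the random range and ribosomal proteins below it. The first lay at percentile 99.77 by its median but 93.5 by its mean, the second at 99.7 and ribosomal proteins at 63.8. None of them lay beyond the range on the opposite side, as the other sign would require. In the authors' deposited table rmf was called positive (4.82), and rpoS (0.80), dps (−1.15) and osmY (−1.96) were not called. What keeps the stage open is that ribosomal proteins lay within the range and that no value per library was analysed here. The acid resistance list lay below the range, with 4 of 14 members above 0. It was not among the lists of that expectation and was considered after its value was seen.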
